A study of Mus musculus with 4 samples.

How the data were processed

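The samples were 4 cultures of the mouse colon carcinoma line CT26, each measured on 1 Affymetrix Mouse Gene 2.0 ST array, per the series design text. Per the labels, 1 culture was given DMSO for 24 h, 1 was given 5 µM Senexin B for 24 h, 1 carried the pLKO.1 vector and 1 is named shCDK8. Total RNA was isolated with a column kit and labelled with biotin, per the labels' protocols. The deposited values are log2 expression values, 1 per probe set and array. Per the submitters' processing notes, RMA and Affymetrix Expression Console were used. Their versions and settings, and whether the 4 arrays were normalized together, are not given in the sources used here. RMA subtracts background, equalizes the distributions of the arrays and summarizes probes on the log2 scale. It therefore removes a shift common to all genes, and it compresses differences of genes near the background. The lower quartile (4.82 to 4.89), the median (5.99 to 6.04) and the upper quartile (7.76 to 7.81) were close on the 4 arrays. The signal over background of each probe set and the genome build of the array design were not used here, so no coordinates are given.

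Probe sets were named through the platform annotation. Of 41345 probe sets 23521 had 1 gene symbol, 1814 had several and 16010 had none, and only those with 1 symbol were used for genes. Of the 23521, 23328 matched a gene of the RefSeq table for GRCm38.p6, and 0 symbols needed an update. That table was otherwise used only for the order of neighbouring genes. The named probe sets stood for 22180 genes, of which 1082 had several, and the probe set with the highest mean over the 4 arrays was then taken. A gene was counted as expressed where its highest value over the 4 arrays reached the 40th percentile of all gene values, 5.98, which left 14272 genes.

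With 1 array per group the number of arrays limits the precision: there was no residual spread, no test and no p-value. For each gene the difference of the log2 values was taken for Senexin B minus DMSO and for shCDK8 minus pLKO.1, and expressed genes at least 2-fold apart were counted. The difference of the control arrays, pLKO.1 minus DMSO, was computed the same way and set beside these counts. The controls are not replicates of each other, since 1 carries a vector and the other received solvent, and each shares an array with 1 comparison. A gene low on the DMSO array alone is therefore higher both in the Senexin B comparison and between the controls.

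Before the data were examined, 36 gene lists were fixed. They covered Mediator, matrix metalloproteinases, their inhibitors, other proteases, matrix and adhesion, signalling targets, interferon and antigen presentation genes, cell cycle, histones, lipid synthesis, hypoxia, stress responses, ribosomes, respiration, mesenchymal and epithelial genes, markers of immune, endothelial, fibroblast and liver cells, and reference genes. For each list the median difference of its expressed members was placed among 10000 random lists of the same size, drawn with replacement from 20 bins of mean expression. A list was said to stand apart below percentile 2 or above percentile 98, as a description of these arrays.

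The rule for the genes named was also fixed before the data were examined. It takes all measured members of the Mediator kinase module, the metalloproteinase and the inhibitor lists. Per comparison it takes the 12 expressed genes with the largest positive and the 12 with the largest negative difference. It leaves out predicted or unnamed loci, pseudogenes, small RNAs, and receptor and immunoglobulin segments. Per list it takes up to 4 expressed members with the largest absolute difference. It also takes up to 15 genes per direction that were 2-fold apart the same way in both comparisons, and up to 10 that were 2-fold apart in opposite directions. Of the 98 genes higher with Senexin B and the 36 lower, the exclusions applied to 4 each, and of the 28 higher and 46 lower in shCDK8 to 2 each. Genes named for the difference between the controls were chosen after their values were seen.

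The alternatives fixed beforehand were no filter on low values and a filter at the 60th percentile, a repeated quantile normalization, removal of a lowess trend with a span of 0.3, the mean of a gene's probe sets, genes with a single probe set, thresholds of 1.5-fold and 3-fold, a floor at the 40th percentile, the mean in place of the median of a list, and 5 expression bins. Chosen after seeing the data were the other control array as reference, genes past the threshold against both controls, and the correlation without the interferon list. A value was called moved where it shifted by at least 0.1 on the log2 scale, and a count where it left a factor of 1.5.

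The computation was tested on a simulated pair of arrays built from the means of 14272 genes over the 4 arrays, with normal noise whose SD for the difference was that between the controls, 0.194. Of 100 genes given a 3-fold difference 100% passed the 2-fold threshold, and of 100 given a 1.5-fold difference and 14072 left unchanged 0% did. Between the real controls 14 genes did, so this checks the computation and not how reliable a 2-fold difference is. Of 200 simulated lists with no shift 2.5% lay past the percentile limits, and a list of 25 genes shifted by 0.2 lay at percentile 100. The simulated genes varied independently of each other. Between the real controls 9 of 36 lists lay above the limits and 4 below, so 2.5% is not the rate for real lists. Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.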

Results

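Gene expression was measured in CT26 cells, a mouse colon carcinoma line grown in culture, on 4 Affymetrix Mouse Gene 2.0 ST arrays. One pair of arrays held RNA from cells given the solvent DMSO or 5 µM Senexin B for 24 h. Senexin B is a small-molecule inhibitor of CDK8 and CDK19, the kinases of the Mediator complex, which links transcription factors to RNA polymerase II. The other pair held RNA from the line carrying pLKO.1, a lentiviral vector for short hairpin RNAs, and from the line labelled shCDK8. The series title ties CDK8 to liver metastasis of colon cancer and to the matrix metalloproteinase genes. Each group had 1 array and the labels name no replicates, so no difference could be tested and each value is a difference between 2 arrays on the log2 scale. The array medians over 41345 probe sets were 5.99 for DMSO, 6.04 for Senexin B, 6.02 for pLKO.1 and 6.03 for shCDK8, and Pearson's r between arrays across probe sets lay between 0.982 and 0.990. Of 22180 named genes, 14272 were counted as expressed. The control arrays, pLKO.1 minus DMSO, served as a yardstick: 12 expressed genes were at least 2-fold higher, 2 were at least 2-fold lower, and the SD over genes was 0.194.

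The gene aimed at by the hairpin was read first. Cdk8 stood at 10.69 in DMSO, 10.58 in Senexin B and 10.79 in pLKO.1, and at 9.07 in shCDK8, a difference of -1.72 or 3.31-fold lower than pLKO.1. Cdk19, the other Mediator kinase, was 0.19 higher in shCDK8 and 0.16 higher in Senexin B. The other members of the kinase module were Ccnc, Med12, Med12l, Med13 and Med13l, and each differed by less than 0.3 in both comparisons. The medians of the 7 module genes were -0.093 for Senexin B and -0.075 for shCDK8. Among 26 other Mediator subunits the medians were -0.13 and 0.018. Med30 was the single one at least 2-fold apart, at 2.00-fold lower in shCDK8, followed by Med14 with a difference of -0.59.

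The first comparison asked what inhibition of the Mediator kinases by Senexin B did to the transcripts of CT26 cells. The largest difference was in Ccl11, the eosinophil chemokine eotaxin, which was higher with Senexin B than with DMSO (3.78), from a DMSO value under the expression limit of 5.98. Ccl7, a monocyte chemokine, was 2.84 higher, and Aldh3a1, an aldehyde dehydrogenase, 2.97 higher. Genes for matrix proteins stood among the highest, with Prelp at 2.53, Bgn (biglycan) at 2.41, Dcn (decorin) at 2.29 and Col6a2 at 2.04. In the other direction Akr1c18, which inactivates progesterone, was at -3.66, or -3.27 with its Senexin B value raised to that limit. The selectins Sele and Selp, adhesion receptors for leukocytes, were at -2.22 and -1.49, and the stromelysin Mmp10 was at -2.17. In all, 98 expressed genes were at least 2-fold higher and 36 at least 2-fold lower, with an SD over genes of 0.292. Of these, 69 and 21 were also past 2-fold when set against the pLKO.1 array.

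Further genes at the top of the Senexin B comparison were Scnn1g, a subunit of the epithelial sodium channel (2.97), Scara5, a ferritin receptor (2.86), Lpar4, a receptor for lysophosphatidic acid (2.81), and Slfn2 (2.32). Lower genes included Esm1, an endothelial proteoglycan also made by tumours (-2.10), the aspartoacylase gene Aspa (-2.09), the sodium pump subunit Atp1b1 (-1.86), the peptide hormone gene Apln (-1.69), Tenm3 (-1.54), Sh2d1b1 (-1.52) and Cavin4 (-1.51). Scara5, Slfn2 and Sh2d1b1 lay under the expression limit on the DMSO array, and Aspa and Sh2d1b1 on the Senexin B array, so the sizes of these differences are uncertain. With values under the limit raised to it, Scara5 was at 2.56, Slfn2 at 2.07 and Aspa at -1.93, and Sh2d1b1 showed no difference.

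Of 23 listed matrix metalloproteinases 22 were measured and 12 expressed, and with Senexin B they went both ways. Mmp10 (-2.17) and Mmp13 (-1.52), a collagenase, were at least 2-fold lower. Mmp3 (-0.74) and Mmp9 (-0.59) were lower by at least 1.5-fold. Mmp2, the gelatinase A gene, was 2.08 higher, from a DMSO value just under the expression limit, and Mmp14, whose product activates Mmp2, was 0.64 higher. Against the pLKO.1 array Mmp2 was 1.71 higher but Mmp14 only 0.15, and Mmp14 differed by 0.49 between the controls. For Senexin B minus DMSO the list median was 0.042, at percentile 80.8 of random lists matched on expression. It was -0.37 when the expression filter was set at the 60th percentile. Among the inhibitors of these enzymes Timp3 was 3.41-fold higher (1.77), Timp1 was at -0.83, Timp2 at 0.16 and Reck at 0.25. That list of 4 expressed genes had a median of 0.21 at percentile 98.2, and lay inside the limit after either rescaling of the arrays.

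Extracellular matrix genes as a group lay higher with Senexin B. Of 40 expressed members 27 were above 0, 6 were at least 2-fold higher and none was 2-fold lower. The 6 were Bgn, Dcn, Col6a2, Col12a1 (1.76) and, chosen after their values were seen, Col6a3 (1.45) and Col6a1 (1.40). The list median was 0.19, beside 0.10 for pLKO.1 minus DMSO. Fibroblast markers, of which 4 expressed members are also on the matrix list, had a median of 0.23 over 9 expressed members, with Dcn and the growth factor receptor Pdgfra (1.24) 2-fold higher, Col3a1 at 0.57 and Fap, under the expression limit on both arrays, at -0.46. The median of these markers was 0.11 between the controls. Of the mesenchymal list, with a median of 0.089, Pdgfrb (1.49) was the single gene 2-fold higher. TGF-beta/SMAD targets had a median of 0.060, with 13 of 20 above 0, among them Timp3, Ltbp2 (0.82) and Ldlrad4 (0.69). Their median was 0.12 between the controls and -0.084 for Senexin B minus pLKO.1.

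Interferon-stimulated genes were higher with Senexin B in 33 of 35 expressed members, 8 of them at least 2-fold. The list median was 0.55, with Usp18 at 1.60, Oas2 at 1.54, Gbp7 at 1.47 and Oasl2 at 1.40. The same list had a median of 0.47 in pLKO.1 minus DMSO, with 31 members above 0, and of 0.075 in Senexin B minus pLKO.1. Antigen presentation genes were higher in 14 of 15 members, with a median of 0.32 beside 0.27 between the controls, and Psmb9, an immunoproteasome subunit, stood at 0.96. Among 31 NF-kappaB targets the median was 0.16 and 17 lay above 0. Ccl7, the iron-binding lipocalin gene Lcn2 (1.21) and the acute-phase gene Saa3 (1.18) were at least 2-fold higher, and Ccl2 was at 0.92.

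Cholesterol synthesis genes were higher in 15 of 19 expressed members, with a median of 0.21, Nsdhl at 0.61, Mvd at 0.54 and Hmgcs1 at 0.50. All 24 ribosome biogenesis genes lay below 0, with a median of -0.24, and Ddx21 (-0.44), Bop1 (-0.42) and Rrp12 (-0.40) were the lowest. Heat shock genes had a median of -0.24, with 10 of 11 below 0, Hspb8 at -0.49 and Hsph1 at -0.45. Their median was -0.12 between the controls and -0.091 for Senexin B minus pLKO.1. Targets of p53 had a median of -0.19, with 15 of 23 below 0. Plk3 (-0.65) and Eda2r (-0.64) were lower, while the death receptor gene Fas was 1.23 higher. G1/S genes had a median of -0.15, with 27 of 32 below 0, including Tyms (-0.43) and E2f7 (-0.43). Random lists matched on expression also had medians below 0, at -0.080 for G1/S, -0.077 for ribosome biogenesis, -0.068 for heat shock and -0.062 for p53. The lists lay at percentiles 1.48, 0, 0.39 and 0.24 of these. Of the reference genes 9 of 10 were below 0 as well, so a count below 0 is not by itself a response. Of 5 expressed aryl hydrocarbon receptor targets, with a median of 0.38, Aldh3a1 alone was 2-fold apart, and Cyp1a1, the best known of these targets, lay under the expression limit on both arrays. Stress response genes of the integrated and unfolded protein responses had a median of 0.074, with Cth at 0.86 and Cebpb at 0.81. Of 15 integrins 8 lay above 0 and 7 below, with a median of 0.18 that turned to -0.10 at the 60th percentile filter, Itgb4 at 0.90 and Itgav at -0.59.

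In the Senexin B comparison 12 of 36 gene lists lay above percentile 98 and 4 below percentile 2. Between the controls 9 and 4 did. Set against the pLKO.1 array, the interferon, antigen presentation, matrix, mesenchymal, TGF-beta/SMAD, integrin, inhibitor and heat shock lists no longer stood apart.

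**Figure D1:**
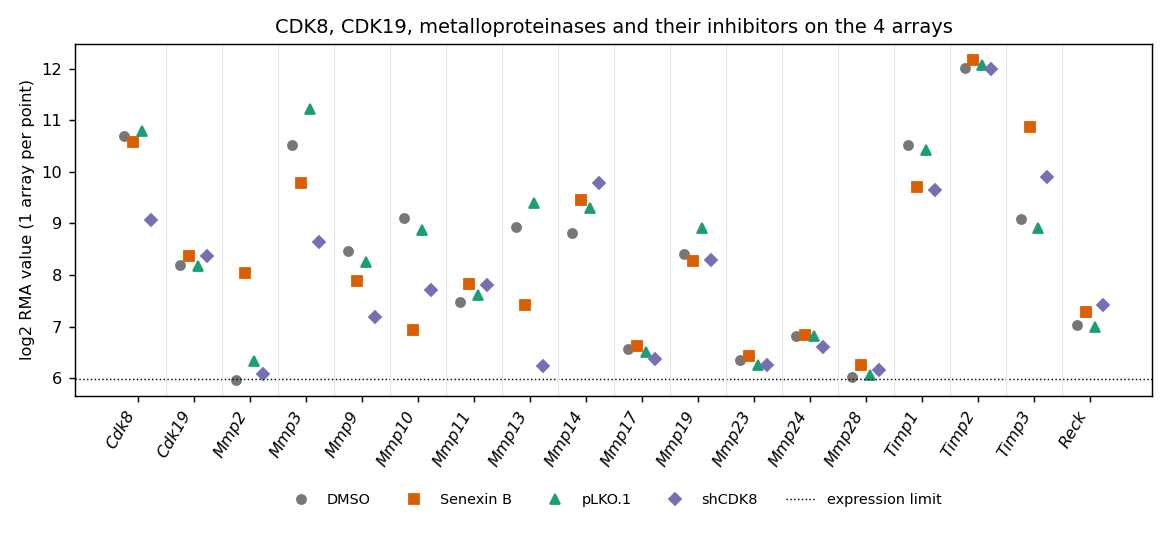
Log2 RMA values (vertical axis) of Cdk8, Cdk19, the expressed matrix metalloproteinases and their expressed inhibitors, with 1 point per array and the expression limit of 5.98 as a dotted line. Cdk8 is lowest on the shCDK8 array (9.07), Mmp3, Mmp10 and Mmp13 are lower on the Senexin B and shCDK8 arrays than on both controls, and Mmp2 is highest on the Senexin B array (8.05).

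The second comparison asked how the line with the CDK8 hairpin differed from the line with the vector. The largest negative differences were those of the metalloproteinase genes Mmp13, 9.02-fold lower in shCDK8 than in pLKO.1 (-3.17), and Mmp3, a stromelysin, 6.04-fold lower (-2.59). Of the other metalloproteinases, which were not among the lowest genes, Mmp10 was at -1.18 and Mmp9, the gelatinase B gene, at -1.06. Egln3, a prolyl hydroxylase that acts on hypoxia-inducible factors, was 4.21-fold lower (-2.07), and the quinone reductase gene Nqo1 was at -1.71. Higher genes were led by Atp1b1 (1.80), the noncoding RNA gene U90926 (1.66), the proteoglycan gene Sdc3 (1.64), the lipase gene Abhd6 (1.43) and Fst, whose product follistatin binds activin (1.37). In all, 28 expressed genes were at least 2-fold higher and 46 at least 2-fold lower, with an SD over genes of 0.263, and 15 and 27 of them were also past 2-fold against the DMSO array.

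The lower genes further held Kcnab2, a potassium channel subunit (-1.89), Gfra2, a receptor of the GDNF family (-1.79), Tlr7, a sensor of single-stranded RNA (-1.51), the intestinal keratin gene Krt20 (-1.44) and the lactate transporter gene Slc16a3 (-1.39). The higher genes further held the Wnt-inducible Ccn4 (1.34), the receptor gene Notch2 (1.30), Gxylt2, a xylosyltransferase that modifies Notch (1.26), Zfp54 (1.30), Dzip1 (1.27), Clca3a1 (1.23) and Prrg4 (1.16). Ccn4, Zfp54 and Clca3a1 lay under the expression limit on the pLKO.1 array, and Tlr7 on the shCDK8 array. Raised to the limit, they gave 1.01 for Ccn4, 0.29 for Zfp54, 0.39 for Clca3a1 and -0.89 for Tlr7.

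Among the 12 expressed metalloproteinases 9 were lower in shCDK8 than in pLKO.1, 4 of them at least 2-fold, and Mmp19 (-0.61) was lower by 1.5-fold. Against the DMSO array Mmp19 was at -0.12, Mmp13 at -2.70, Mmp3 at -1.89, Mmp10 at -1.40 and Mmp9 at -1.27. For shCDK8 minus pLKO.1 the list median was -0.24, at percentile 0.050, beside 0.094 between the controls. With no expression filter it was -0.064 and no longer stood apart. Mmp14 was 0.48 and Mmp11 0.18 higher, and Mmp2 was at -0.26. The remaining expressed members Mmp17, Mmp23, Mmp24 and Mmp28 differed by less than 0.3 in both comparisons. Mmp13, Mmp3 and Mmp10 are neighbours within a cluster of 10 metalloproteinase genes in the RefSeq annotation of GRCm38.p6, in the order Mmp13, Mmp12, Mmp1b, Mmp3, Mmp1a, Mmp10, Mmp8, Mmp27, Mmp20 and Mmp7. The other 7 were not expressed by the limit used, nor were Mmp16, Mmp21, Mmp25 and Timp4. Timp3 was 0.99 higher, Reck 0.43 higher and Timp1 at -0.78, with a median of 0.18 for the inhibitors. Genes of the plasminogen system, 5 of them expressed, had a median of 0.16, which is the value of Plg, under the expression limit on both arrays. The other 4 lay above 0, with Plau, the urokinase gene, at 0.67. For Senexin B the median was -0.21, with Plaur at -0.52.

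Interferon-stimulated genes were lower in shCDK8 than in pLKO.1 in 30 of 35 expressed members, 4 at least 2-fold, with a median of -0.35. Oasl1 was at -1.47, Oas2 at -1.36, Irf7, the transcription factor of the interferon response, at -1.20, and Oasl2 at -1.16. Against the DMSO array the same list had a median of 0.13, at percentile 99.4, and so stood apart in the opposite direction. Targets of p53 had a median of 0.31, with 18 of 23 above 0, Eda2r at 0.81, Cd80 at 0.80 and Trp53inp1 at 0.70, and between the controls of -0.032. Cholesterol synthesis genes had a median of -0.23, with 13 of 19 below 0 and Ebp at -0.68, and between the controls of 0.092. Against the DMSO array the cholesterol median was -0.087, at percentile 16.3. Stress response genes had a median of -0.20, with 19 of 26 below 0, Slc7a5 at -0.53 and Mthfd2 at -0.51, and between the controls of -0.14. Ribosome biogenesis genes were below 0 in 23 of 24 members, with a median of -0.13 and Heatr1 at -0.32. G2/M genes had a median of 0.094, with 22 of 32 above 0 and Cenpe at 0.36, and between the controls of -0.15. Against the DMSO array the G2/M median was -0.086.

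In other lists single genes were far apart while the medians stayed inside the percentile limits. Of 40 matrix genes Col3a1 alone was 2-fold apart in shCDK8, at -1.27, with a list median of 0.0081. Of 25 hypoxia and glycolysis genes Egln3 and Slc16a3 were 2-fold lower and Ndrg1 was at -0.75, with a median of 0.0032. Of the NRF2 targets Nqo1 was lower and the glutathione transferase gene Gsta4 1.15 higher, with a median of -0.085. The fatty acid elongase gene Elovl5 was at -1.12 in a list whose median was -0.091. Mesenchymal genes had a median of 0.11, at percentile 97.7, with Pdgfrb at -1.25 and the smooth muscle actin gene Acta2 at 0.93. Fibroblast markers had a median of -0.16, at percentile 2.26, with 7 of 9 below 0. In the shCDK8 comparison 2 lists lay above percentile 98 and 5 below percentile 2. Set against the DMSO array, the metalloproteinase, cholesterol and G2/M lists no longer stood apart.

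**Figure D2:**
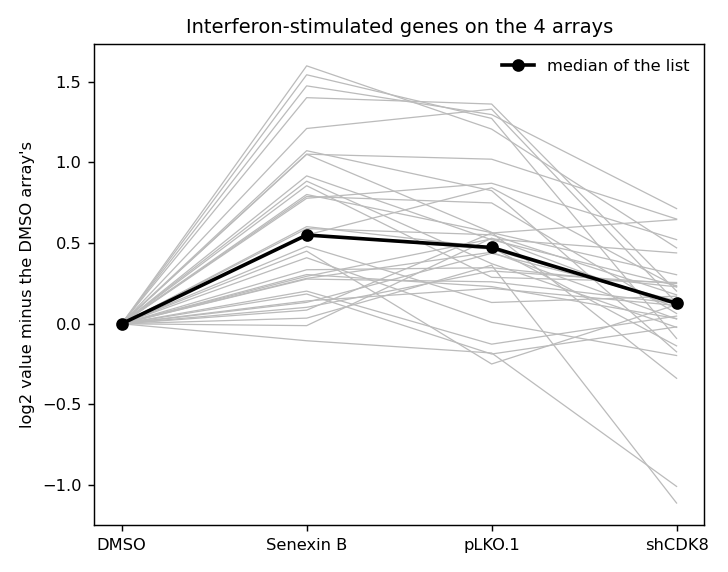
Log2 value of each of 35 expressed interferon-stimulated genes minus its value on the DMSO array (vertical axis) on the 4 arrays, with 1 grey line per gene and the list median in black. The median is 0.55 for Senexin B, 0.47 for pLKO.1 and 0.13 for shCDK8.

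**Figure D3:**
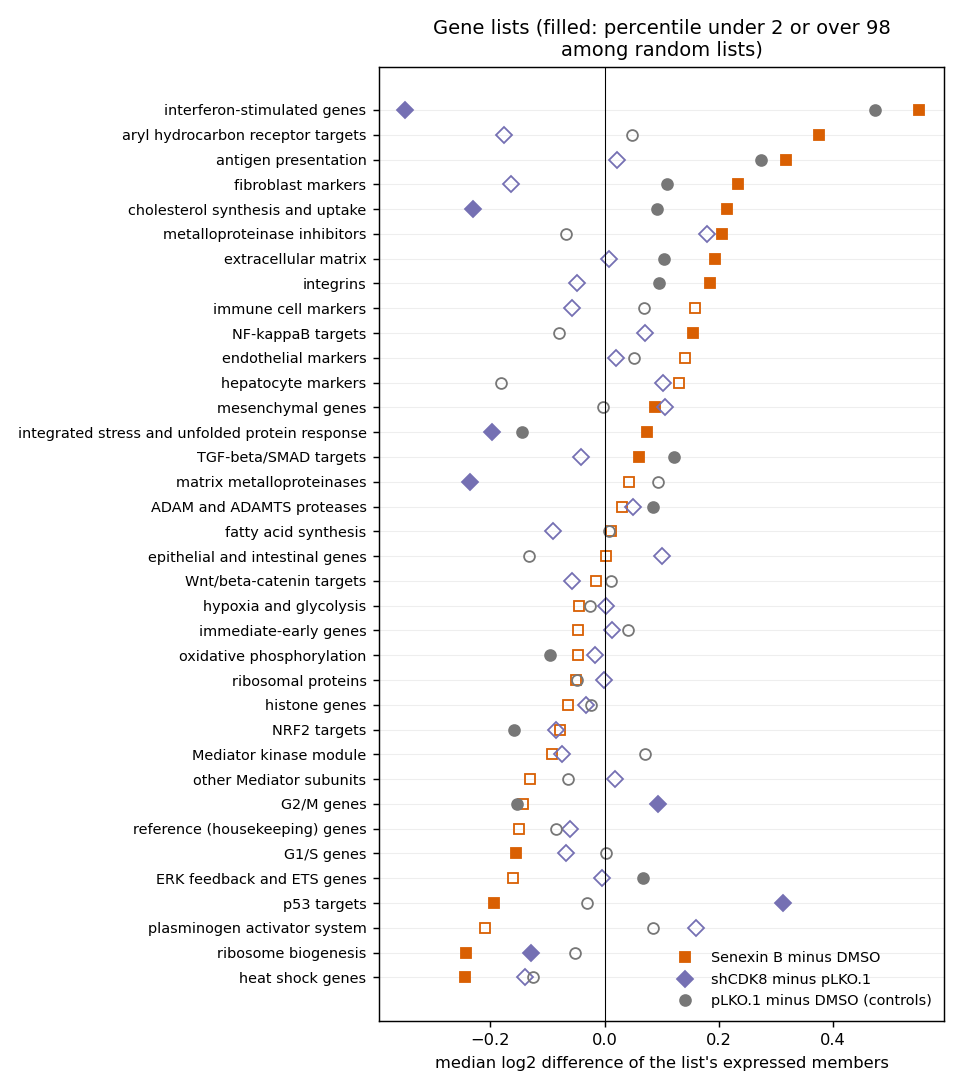
Median log2 difference (horizontal axis) of the expressed members of each of 36 gene lists (vertical axis) for Senexin B minus DMSO, shCDK8 minus pLKO.1 and the controls, with filled symbols where the median lay under percentile 2 or over percentile 98 of 10000 random lists. Interferon-stimulated genes lie at 0.55 for Senexin B, 0.47 for the controls and -0.35 for shCDK8.

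The arrays allowed the inhibitor and the hairpin to be compared without a shared control, since the comparisons have no array in common. At least 2-fold lower in both were Mmp13, Mmp10, Apln, Neto2 (-1.27 and -1.33, Senexin B first) and Polr2l, a subunit of RNA polymerases (-1.39 and -1.15). Polr2l lay under the expression limit on the Senexin B and shCDK8 arrays and Neto2 on the shCDK8 array. With values raised to the limit Polr2l was at -0.94 and -0.93, no longer 2-fold, and Neto2 at -1.05 in shCDK8. Independent lists of these sizes would share 0.116. Against the other control Neto2 was at -0.65 with Senexin B and Apln at -0.83 in shCDK8, so 3 of the 5 were past 2-fold against both controls. At least 2-fold higher in both were Anxa8, a membrane-binding annexin (1.31 and 1.16), and Gpnmb, a transmembrane glycoprotein gene (2.04 and 1.06), against 0.192 for independent lists. Anxa8 lay under the expression limit on the pLKO.1 array and was at 0.96 in shCDK8 with that value raised to it. Gpnmb also differed between the controls, at 1.60, and neither gene was past 2-fold against both controls in both comparisons. Timp3 was at 1.77 and 0.99, and Timp1 was lower in both.

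Other genes were 2-fold apart in opposite directions. Higher with Senexin B and lower in shCDK8 were 8 genes, against 0.316 for independent lists: Gfra2 (1.84 and -1.79), Lpar4 (2.81 and -1.17), Pdgfrb (1.49 and -1.25), Adgrg6 (1.56 and -1.14), Sox9 (1.61 and -1.003), Oas2, Oasl2 and Irf7. Adgrg6 lay under the expression limit on the shCDK8 array and was at -0.78 with that value raised to it. Of the 8 only Gfra2, Pdgfrb and Adgrg6 were past 2-fold against both controls in both comparisons. Against the other control Irf7 turned in both (-0.12 and 0.13), Oasl2 was at 0.040 and 0.20, and Oas2 at 0.27 and -0.091. There Sox9 was at 0.93 and -0.32, and Lpar4 at 2.63 and -0.99. Each of these values is the paired difference shifted by pLKO.1 minus DMSO, which was 1.33 for Irf7, 1.36 for Oasl2 and 1.27 for Oas2. They show how far a result depends on the control chosen and test no cause. Atp1b1 went the other way (-1.86 and 1.80) and was past 2-fold against both controls. Across the expressed genes Pearson's r between the comparisons was 0.0078 and Spearman's rho 0.054, genes not being independent replicates. Pairing the same arrays in the other possible ways gave r of 0.10 and -0.077. Of the genes 2-fold apart with Senexin B 45.5% had the same sign in shCDK8, and of those 2-fold apart in shCDK8 39.2% had the same sign with Senexin B, beside 52.5% of all expressed genes.

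**Figure D4:**
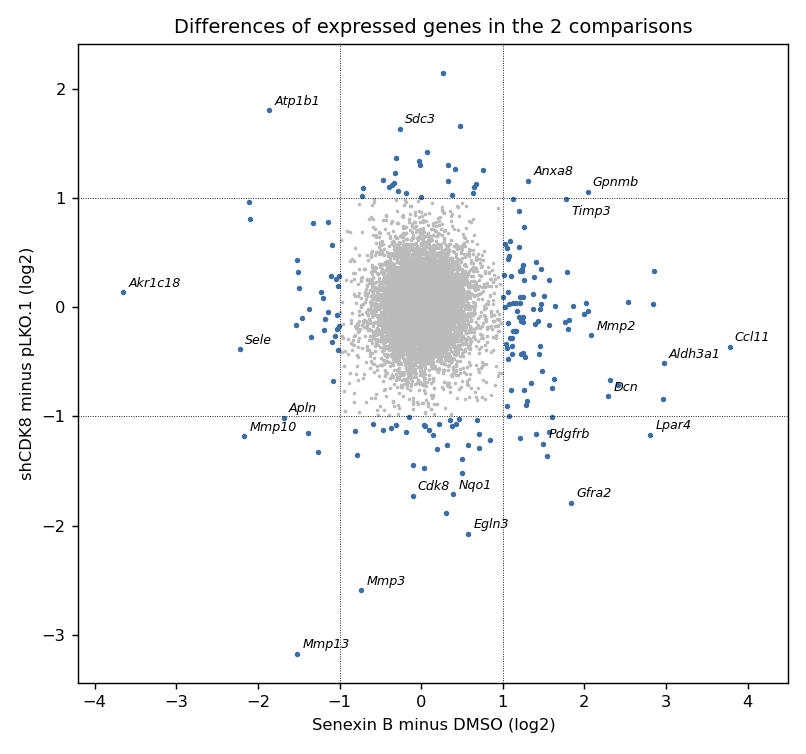
Log2 difference of each expressed gene for Senexin B minus DMSO (horizontal axis) and shCDK8 minus pLKO.1 (vertical axis), with dotted lines at 2-fold and genes past them in blue. Mmp10 (-2.17 and -1.18) and Mmp13 (-1.52 and -3.17) lie at the lower left, and Gfra2 (1.84 and -1.79) at the lower right.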

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

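The tests in this part were chosen after the result was seen, except the share of same signs and the removal of the lowess trend, which was an alternative fixed beforehand, although its bound for the interferon-stimulated genes was set afterwards. Of the genes 2-fold apart in opposite directions, Atp1b1 was at -1.86 with Senexin B and 1.80 in shCDK8, Gfra2 at 1.84 and -1.79, Pdgfrb at 1.49 and -1.25, Lpar4 at 2.81 and -1.17, Adgrg6 at 1.56 and -1.14, and Sox9 at 1.61 and -1.003. Oas2 stood at 1.54 and -1.36, Irf7 at 1.21 and -1.20, and Oasl2 at 1.40 and -1.16. Of these 9 genes Atp1b1, Gfra2, Pdgfrb and Adgrg6 were past 2-fold against both controls in both comparisons. Gene lists with medians apart in opposite directions were the interferon-stimulated genes (0.55 and -0.35), p53 targets (-0.19 and 0.31), cholesterol synthesis (0.21 and -0.23) and the stress response genes (0.074 and -0.20). Against the other control the p53 targets (-0.16 and 0.23) and the stress response genes (0.16 and -0.36) still stood apart in these directions. Cholesterol synthesis did so with Senexin B but not in shCDK8 (-0.087), and the interferon-stimulated genes in neither comparison. Ribosome biogenesis genes instead stood apart on the lower side in both comparisons (-0.24 and -0.13), and also against the other control (-0.20 and -0.17). Each is a difference between single arrays, and whether the comparisons differ was not tested.

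The interferon-stimulated genes were weighed first. For shCDK8 minus pLKO.1 random lists matched on expression had a median of 0.010, so genes at this level were not shifted as a group. The list median was still -0.36 after the lowess trend was removed. That step moved the median of the expressed genes by only -0.0060, so it could hardly change the list and is no separate test. Against the DMSO array the shCDK8 median was 0.126, and the Senexin B median against the pLKO.1 array was 0.0747, beside -0.35 and 0.55 against the paired controls. Changing the reference adds or takes off the distance of the control arrays from each other by arithmetic, so these values cannot test a cause. That distance is a candidate explanation for either direction taken alone. It would mean a high level on the pLKO.1 array for the hairpin, or a low level on the DMSO array for the inhibitor. The list median of shCDK8 minus Senexin B, which uses no control array, was -0.41. Control levels leave that value untouched, so they cannot account for both directions in full. Whether the vector, the culture or the array set those levels stays open, as does an effect of the kinases themselves.

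The higher matrix genes with Senexin B were weighed next. The 6 genes at least 2-fold higher, picked by that difference, all stayed so after the lowess trend was removed. That step moved the median of the expressed genes by only 0.027, so it could hardly bring genes picked at 1.40 or more below 2-fold. Against the pLKO.1 array 6 of 6 were 2-fold higher too, so they were higher on the Senexin B array than on either control. Changing the reference here again only adds or takes off the distance of the controls and tests no cause. For the list as a whole a low DMSO array stays a candidate explanation: its median was 0.19 against DMSO but 0.0601 against pLKO.1, where it no longer stood apart, and 0.10 between the controls. Fibroblast RNA in the Senexin B sample cannot be told apart from a response of the CT26 cells: the 8 expressed fibroblast markers other than Dcn had a median of 0.224 and ranged from -0.46 to 1.24, below the lowest of the matrix genes at 1.40, but only 2 of them lay between the expression limit and the median of expressed genes on the DMSO array, where a level of the line's own would not hide a small share. The number of Senexin B arrays is 1, so a culture or array effect cannot be told apart from the inhibitor, whose own effect stays untested.

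The low correlation between the comparisons was weighed last. The opposite interferon-stimulated genes do not account for it, since r without them was 0.0197. Of the genes 2-fold apart with Senexin B 45.5% had the same sign in shCDK8, beside 52.5% of all expressed genes. A share under 60% had been set beforehand to count against array noise that hides a shared response, but noise among the 2-fold genes themselves would also split their signs evenly, and with 1 array per group no noise was measured, so this stays open. Differences between inhibiting both kinases for 24 h and lowering Cdk8 alone in a separate line may contribute and stay untested.

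Probe sets without a single gene name entered no comparison of genes. Of 8283 above the expression limit 179 were at least 2-fold lower and 120 higher with Senexin B, and 177 lower and 134 higher in shCDK8. Between the controls 58 were lower and 213 higher. Over both directions the controls were thus 2-fold apart in a similar number of these probe sets, and only the split by direction differed.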

How the results depend on the processing

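With no replicates the settings show only how far the values depend on the computation, and causes of the shifts were not tested. The named 2-fold differences, 93 in all, stayed past 2-fold under no filter, repeated quantile normalization, lowess removal and the mean of probe sets. So did 84 of 84 at the 60th percentile filter, 91 of 91 for genes with a single probe set, 83 of 93 with the floor and 65 of 93 with the other control as reference. No scaling moved the median of all genes by 0.1. Of the list calls, those lost under some of 8 planned settings were G1/S (kept in 6), TGF-beta/SMAD (5), integrins (3), mesenchymal (6), inhibitors (5) and p53 (7) with Senexin B and metalloproteinases (7) in shCDK8. Without a filter 52 genes were higher in shCDK8, 24 higher and 11 lower between the controls, and the medians were -0.064 for the metalloproteinases in shCDK8 and 0.16 for the inhibitors with Senexin B. At the 60th percentile 1 gene was lower between the controls, the metalloproteinase medians were -0.37 (Senexin B, now at percentile 0.060) and -0.84 (shCDK8), and the integrins turned to -0.10 with Senexin B. The inhibitor list with Senexin B was at 0.21 after quantile normalization and 0.22 after lowess removal, both inside percentile 98, and at 0.34 by the mean. The metalloproteinase means were -0.14 and -0.71. At 1.5-fold 336 genes were higher and 235 lower with Senexin B, 238 and 264 in shCDK8, and 86 and 62 between the controls. Shared at 1.5-fold were 16 higher, 23 lower, 41 higher with Senexin B and lower in shCDK8, and 18 the other way. At 3-fold the counts were 26 and 7, 4 and 7, and 1 and 0, with 0 higher in both, 0 lower in both 1 higher with Senexin B and lower in shCDK8, and 1 the other way. Against both controls 21 genes were lower with Senexin B, and 15 higher and 27 lower in shCDK8, and the comparisons shared 0 higher, 3 lower, 3 higher with Senexin B and lower in shCDK8, and 1 the other way. With the other control as reference, a choice made after seeing the data, Cdk8 was at -0.21 with Senexin B and -1.62 in shCDK8, and the metalloproteinases were at -0.16 in shCDK8 and the inhibitors at 0.20 with Senexin B, both inside the percentile limits. Of the lists that stood apart and the named genes 2-fold apart, TGF-beta/SMAD targets (-0.084), Irf7 (-0.12) and Phf11d (-0.038) turned with Senexin B, and interferon-stimulated genes (0.13), G2/M genes (-0.086), Irf7 (0.13), Oas1g (0.21) and Oasl2 (0.20) in shCDK8. Low signal limits genes near the expression limit, where the floor took 10 of the 93 differences below 2-fold. No paired analysis was possible because each group had 1 array and no result comes from a test.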

Other observations

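The control arrays differed in a small set of genes, which were chosen after their values were seen. Gpnmb was 1.60 higher in pLKO.1 than in DMSO. Interferon-inducible genes were higher too, with Oasl2 (1.36), Irf7 (1.33), Gbp7 (1.30), Oas2 (1.27), Oas1g (1.24), Phf11d (1.24), Usp18 (1.21) and Xaf1 (1.02). Ndst4 was 1.01 higher, the small RNA genes Mir142 (1.56) and Mir125b-1 (1.09) completed the 12 genes at least 2-fold higher, and the chemokine gene Cxcl5 (-1.08) and the locus 9030624G23Rik (-1.08) were the 2 lower ones. Phf11d and Mir142 lay under the expression limit on the DMSO array and 9030624G23Rik on the pLKO.1 array. Raised to the limit, they gave 0.85 for Phf11d, 1.46 for Mir142 and -0.081 for 9030624G23Rik, so Phf11d and 9030624G23Rik were no longer 2-fold apart. Among the genes 2-fold higher with Senexin B 8 also had controls 2-fold apart, and 6 of the 46 genes lower in shCDK8 did. Lists that stood apart between the controls were higher for ADAM and ADAMTS proteases (0.085), matrix (0.10), integrins (0.096), TGF-beta/SMAD targets (0.12), interferon-stimulated genes (0.47), antigen presentation (0.27), ERK feedback and ETS genes (0.068), cholesterol synthesis (0.092) and fibroblast markers (0.11). They were lower for G2/M genes (-0.15), stress response genes (-0.14), NRF2 targets (-0.16) and oxidative phosphorylation (-0.095).

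Signalling lists held single genes far apart while their medians stayed inside the percentile limits. Immediate-early genes had medians of -0.046 with Senexin B and 0.013 in shCDK8, with Egr1 at -1.35 and Klf4 at 1.21 with Senexin B. ERK feedback genes had medians of -0.16 and -0.0046, and Dusp5 (-0.99 and 0.62) and Spry2 (-0.59 and 0.81) lay on opposite sides in the comparisons. Wnt/beta-catenin targets had medians of -0.016 and -0.057, with the Wnt antagonist gene Apcdd1 lower in both (-0.94 and -0.54) and Axin2 at 0.55 and -0.23. Hypoxia and glycolysis genes had a median of -0.045 with Senexin B, with Vegfa at 0.86. NRF2 targets had a median of -0.077 there, with the heme oxygenase gene Hmox1 at -1.08 and at -0.68 in shCDK8. Among ADAM and ADAMTS proteases, with medians of 0.030 and 0.049, Adamts7 (0.95) was higher with Senexin B and Adamts9 lay at 0.66 and -0.77.

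Further lists also stayed inside the percentile limits in the comparisons given here. Fatty acid synthesis genes had a median of 0.011 with Senexin B, with Fasn at -0.62 and Fads2 at 0.63. Oxidative phosphorylation genes had medians of -0.047 with Senexin B and -0.016 in shCDK8, ribosomal protein genes of -0.051 and -0.0016, histone genes of -0.064 and -0.032, and reference genes of -0.15 and -0.060. Rps15 was at -1.08 in shCDK8, where it lay under the expression limit. G2/M genes had a median of -0.14 with Senexin B, G1/S genes of -0.067 in shCDK8 and heat shock genes of -0.14. Integrins (-0.048), TGF-beta/SMAD targets (-0.042), NF-kappaB targets (0.071), antigen presentation genes (0.023) and aryl hydrocarbon receptor targets (-0.18) stayed inside the limits in shCDK8. Epithelial and intestinal genes had medians of 0.0018 and 0.10, with Krt20 at -1.44 in shCDK8.

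Beside the fibroblast list, of which 9 of 10 members were expressed, fewer markers of other cell types were. Of 18 immune markers 6 were expressed, with medians of 0.16 and -0.057 and Nkg7 at 0.51 and -0.45. Of 10 endothelial markers 6 were expressed, with medians of 0.14 and 0.019 and Pecam1 at 0.27 and -0.01. Sele, Selp and Esm1, better known from endothelium, lay above the expression limit on all 4 arrays, and were lowest with Senexin B (7.96, 8.51 and 7.17). Of 11 hepatocyte markers 5 were expressed, with medians of 0.13 and 0.10 and Apoa1 at 0.13 in both. Some of the markers counted lay close to the limit of 5.98, such as Vwf (5.87 to 6.06) and Ahsg (5.98 to 6.28). Cd79a passed it only on the Senexin B array (6.01), while Cd68 lay well above it (8.82 to 9.15). Passing the limit therefore does not by itself show that CT26 cells express a marker.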
